A study of Drosophila yakuba and Drosophila santomea and Drosophila yakuba x Drosophila santomea with 18 samples.

How the data were processed

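Total RNA of whole 1-day-old adult males, about 30 males per sample, was hybridised to a NimbleGen expression array in 1 colour (Cy3). The 18 arrays cover 3 isofemale lines of D. yakuba (the genome project strain, Cameroon 115 and Bosu), 3 lines of D. santomea (ST04, ST18 and Quija) and the F1 hybrid males of both cross directions between the genome strain and ST04. Each line has 2 arrays and each hybrid 3, which the labels call biological replicates. The labels write the hybrids as genome project x ST04 and the reverse without saying which parent is the mother. They are called F1 genome x ST04 and the reciprocal F1 here.

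The scanner files hold the fluorescence intensity of each spot, extracted with NimbleScan 2.3.78, per the file headers. These deposited intensity values are not background corrected and not normalised between arrays, as the random control spots show. The mismatch column is 0 throughout and was not used. The value table holds log2 expression per gene, made by the authors with RMA per the submitters' processing notes, for 11530 genes. The settings of that RMA run are not given in the sources used here. The array carries 389307 spots: 12437 genes with a median of 10 probes and 3 spots per probe, 1500 spots of 5 control genes, and 14703 random control spots.

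The intensities were background corrected by normexp with an offset of 50, converted to log2, and quantile normalised over the 18 arrays. The 3 spots of each probe were averaged, and the probes of each gene were summarised by median polish. All 12437 genes were kept. The resulting gene values, each centred on its gene, correlated with the authors' table across genes and arrays at r = 0.984. No identifier on the array matched any of the 16150 genes of the reference table for D. yakuba. Genes therefore have no names or chromosomes here, and they are given by their array number and the FBgn code in the array identifier. The planned test of X linkage and the planned tests of fixed gene lists could not be run for this reason. The planned filter on probes with more than 1 genomic match was not run, since no probe sequences or genome were used here.

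Groups were compared with limma on log2 values, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. Species divergence compared the means of 3 lines against 3 lines. All other comparisons used 1 fit of the 18 arrays with a mean per group and a shared residual. The mid-parent is the mean of the log2 values of the genome strain and ST04, so additivity is meant on the log2 scale. A hybrid additive on the intensity scale would lie above it where the parents differ. A gene counts as beyond both parents when the hybrid was called against each parent in the same direction. Named genes follow a rule fixed before the data were examined: among genes called whose groups overlap in no array, those with the largest log2 difference. Since no names could be matched, at most 2 that rose and 2 that fell are given per main comparison.

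Parental position places a hybrid array between the parents for each gene, as (hybrid minus ST04) divided by (genome strain minus ST04). A value of 0 is the ST04 level and 1 the level of the genome strain. It was taken as the median over genes that limma called between the D. santomea and D. yakuba arrays of the 4 lines that were not crossed, with a parental log2 difference of at least 1 in the same direction. That fit takes its spread between 8 arrays rather than between lines, so these genes are not calls of species divergence; in the first batch it holds 1 line per species. The hybrids were compared by exact permutation of the arrays.

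Several choices were made after the data were seen. The arrays fall into a first batch of 12 and a second batch of 6 by the array numbers in the file headers. The boundary was set after the correlations between arrays were seen. The second batch holds the Bosu and Quija lines and the third array of each hybrid. Batch as a block was planned, while the fit of the first batch alone, the second ST18 array moved to the second batch, and the centring of each array on its median deviation were added. In place of chromosomes, genes were split at the longest unused stretch of array numbers, 465 numbers long, into a lower block of 10444 and an upper block of 1993 genes. The next longest unused stretch has 453 numbers. Genes named on the array as lacking a D. melanogaster ortholog (154) or as masked (1146) formed further groups. Shares of calls were compared by two-sided Fisher's exact tests for 6 comparisons per group, adjusted over these 6 and separately for calls in either direction, higher and lower. Genes are not independent replicates, which these tests assume.

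Other alternatives tried were no background correction, normexp with an offset of 0, median scaling, the authors' table, the mean of the probes, leaving out the 25% of genes with the lowest mean, a stricter threshold of 0.01, an added minimum of 1.5-fold, replicate number as a block, leaving out each array, and leaving out each line. Further ones were at least 80% of the probes sharing the sign of the gene, a fit of the 10 arrays of parents and hybrids, other units of replication for the species, a logistic model with the mean log2 value, and position genes called between the crossed lines.

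The steps were tested on simulated data with 200 changed genes of 12437. In the tests of hybrids both simulated parents had the same mean, and no batch was simulated. The shares recovered need not hold where the parents differ. False calls made up 5.88% of the calls for the species and 0.602% and 0.585% for F1 genome x ST04 and the reciprocal F1 beyond both parents. They made up 6.22% for F1 genome x ST04 against the mid-parent and 7.61% for the reciprocal F1 minus F1 genome x ST04. At a log2 change of 1, species divergence recovered 50% of the changed genes, against 94% for each hybrid beyond both parents, 96% for F1 genome x ST04 against the mid-parent and 94% for the reciprocal F1 minus F1 genome x ST04. At a log2 change of 0.5 these shares were 0% for the species, 38% and 48% for F1 genome x ST04 and the reciprocal F1 beyond both parents, 68% for F1 genome x ST04 against the mid-parent, and 70% for the reciprocal F1 minus F1 genome x ST04. The analysis used R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The number of arrays limits the precision of every value.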

Results

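The series measured gene expression in whole adult males of 2 sister species, D. yakuba and D. santomea, and of their F1 hybrids in both cross directions. According to its title, it addresses a large effect of the X chromosome. The 18 arrays form 8 groups: 6 lines with 2 arrays each and 2 hybrid groups with 3 arrays each. The median intensity of gene spots per array ranged from 1826 to 2824. Between 79.2% of genes, in replicate 2 of the reciprocal F1, and 94.2%, in replicate 1 of Bosu, had a median probe above the 95th percentile of the random control spots of their array. No array identifier could be paired with a gene name, since the files do not pair them and the reference table matched 0 of them.

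The principal component scores separated the arrays first by species and, among the hybrids, by cross direction. The first component held 30.5% of the variance. All D. yakuba arrays and all F1 genome x ST04 arrays lay on 1 side of it, and all D. santomea arrays and all reciprocal F1 arrays on the other. Replicates 1 and 2 of the reciprocal F1, at -28.3 and -29.3, lay beyond every D. santomea array (-17.4 to -24.3), and replicate 3 lay among them at -22.0. The third array of each hybrid, in the second batch, lay apart from its other replicates on the second component, which held 21.2%.

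**Figure D1:**
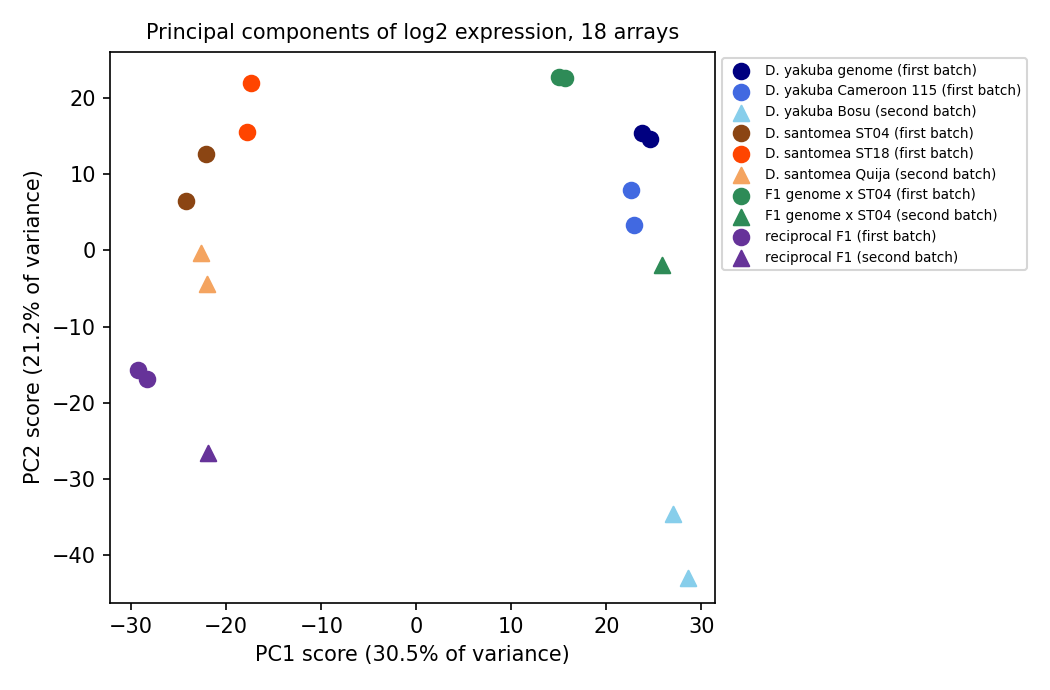
Scores of the 18 arrays on the first (horizontal) and second (vertical) principal component of log2 expression, coloured by group; circles are arrays of the first batch and triangles arrays of the second. F1 genome x ST04 lies on the D. yakuba side of the first component (30.5% of the variance) and the reciprocal F1 on the D. santomea side.

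Species divergence compared 3 D. santomea lines with 3 D. yakuba lines. In D. santomea 125 genes were higher and 187 lower, 312 of 12437 in all, with a median absolute log2 difference of 1.19 among the higher and 1.12 among the lower genes. Gene dyak_455 (FBgn0033065) averaged log2 13.63 ± 0.24 in D. santomea and 9.05 ± 0.34 in D. yakuba (SD, n = 3 lines), a 23.9-fold difference (limma adjusted p = 4.9e-04). Gene dyak_9233 (FBgn0051219) averaged 11.29 ± 0.82 against 7.66 ± 0.47 (limma adjusted p = 0.00915). No fold is given for it, since 2 of the 6 D. yakuba arrays were above the random control spots and the others were not. Gene dyak_474 (FBgn0028853) averaged 7.23 ± 0.19 in D. santomea and 12.76 ± 0.95 in D. yakuba (limma adjusted p = 0.00269). Gene dyak_3171 (FBgn0028949) averaged 7.13 ± 0.12 against 12.53 ± 0.55 (limma adjusted p = 4.9e-04). Neither rose above the random control spots in any of the 6 D. santomea arrays, which puts their signal at least 31.7-fold and at least 27.0-fold lower there. The probes were made for D. yakuba, and weaker binding of D. santomea transcripts would also lower the signal. It was not tested for these genes, for the 312 calls or for the difference between the crossed lines.

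The count of genes called in species divergence depended on the unit of replication and on single lines. It was 408 with batch as a block and 48 in the first batch, of which 37 were among the 312, and dyak_9233 was no longer called there (adjusted p = 0.0674). The second batch holds 1 line per species and allows no test, but 47 of the 48 genes had the same sign in it. The count ranged from 64 to 113 when the genome strain, Cameroon 115, ST04, ST18 or Quija was left out and was 244 without Bosu. It was 8691 with replicate number as a block, a fit that takes its spread between arrays of the same line. Of the called genes 40.1% were higher in D. santomea, and 50.2% under median scaling.

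Lines of the same species also differed. Among the 3 D. yakuba lines 8107 genes differed, and among the 3 D. santomea lines 5766 (limma F test, adjusted p under 0.05). Bosu stood farthest from the other D. yakuba lines: the SD over genes of its log2 difference was 0.60 to the genome strain and 0.55 to Cameroon 115, against 0.40 between those lines. Both species have 1 line in the second batch, Bosu and Quija. With batch as a block, 7511 and 6621 genes differed. In the first batch, which compares the genome strain with Cameroon 115 and ST04 with ST18, 4915 and 4763 genes differed.

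The crossed lines differed at 5434 genes, 2892 higher and 2542 lower in ST04 than in the genome strain, with median absolute log2 differences of 0.51 and 0.59. Higher genes made up 53.2% of these calls, but 45.3% with each array centred and were the fewer among differences of at least 1.5-fold (1115 higher, 1309 lower). F1 genome x ST04 stayed closer to the genome strain: it differed from that parent at 2029 genes (1076 higher, 953 lower) and from ST04 at 4700 (2372 higher, 2328 lower). The reciprocal F1 differed from the genome strain at 5506 genes (3346 higher, 2160 lower) and from ST04 at 3588 (1903 higher, 1685 lower). Of the 5434 genes that differed between the parents, F1 genome x ST04 was called against ST04 alone at 2759 (50.8%), against the genome strain alone at 667, between both at 718 and beyond both at 173. The reciprocal F1 was called against the genome strain alone at 2308 (42.5%), against ST04 alone at 972, between both at 760 and beyond both at 671.

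All 4 parental arrays are in the first batch. The block therefore leaves the difference between the parents unchanged and alters only the residual spread it is tested against. Batch as a block gave counts of 7193 between the parents, 3428 and 6182 for F1 genome x ST04 against the genome strain and ST04, and 7042 and 4918 for the reciprocal F1. In the first batch alone they were 7826, 3660, 6693, 7563 and 5465 in the same order. F1 genome x ST04 against the genome strain fell to 856 without replicate 1 and to 880 without replicate 2 of the genome strain. The reciprocal F1 count was 3666 against the genome strain without that line's replicate 1, and 2272 against ST04 without replicate 1 of ST04. The genes at which the reciprocal F1 was called against the genome strain alone numbered 1412 and 1434 without replicate 1 and replicate 2 of that line. In F1 genome x ST04 the 667 genes of this kind became 273 and 276 without these arrays, 1143 with batch as a block and 1111 in the first batch. The 972 genes at which the reciprocal F1 was called against ST04 alone became 577 without replicate 1 of ST04. Higher genes made up 60.8% of the calls of the reciprocal F1 against the genome strain, 43.9% with each array centred and 36.1% among differences of at least 1.5-fold; against ST04 they made up 53.0%, but 44.4% with each array centred and 36.5% at 1.5-fold. For F1 genome x ST04 against ST04 they made up 50.5%, but 43.0% under median scaling, 43.9% with batch as a block and 63.1% at 1.5-fold. Against the genome strain they made up 53.0%, but 48.4% with each array centred and 48.9% with batch as a block.

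Departure from additivity on the log2 scale was called at more genes in the reciprocal F1. F1 genome x ST04 differed from the mid-parent at 2389 genes, 1503 higher and 886 lower, and the reciprocal F1 at 3834, 2212 higher and 1622 lower. The difference between these counts was not tested as such. The counts with batch as a block were 3648 and 5143, and in the first batch 3988 and 5636. The majority direction was not stable: higher genes made up 62.9% of the calls of F1 genome x ST04 but 49.6% with batch as a block, and 57.7% of the calls of the reciprocal F1 but 38.8% with each array centred and 19.4% among differences of at least 1.5-fold.

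**Figure D2:**
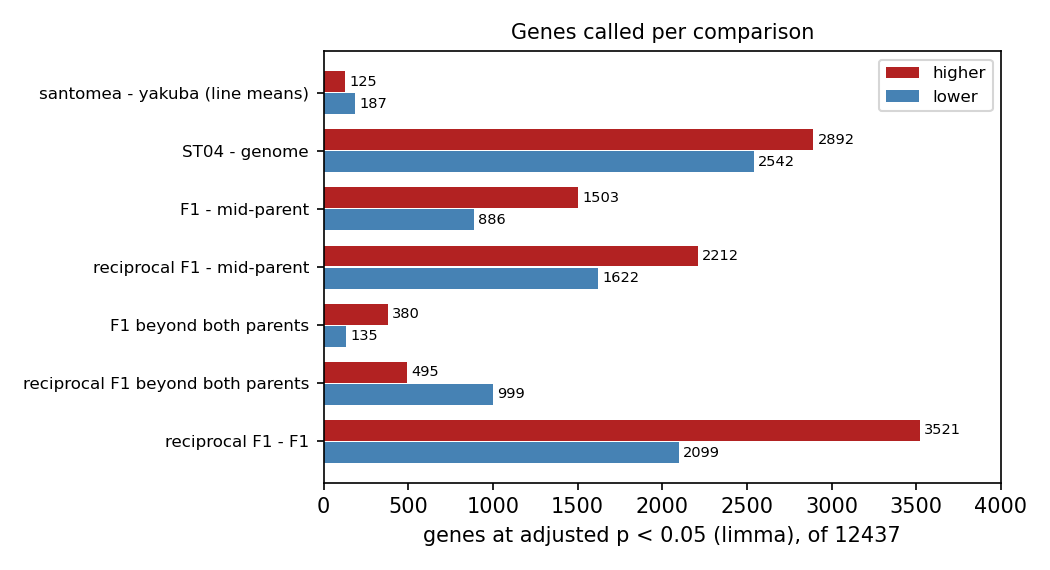
Number of genes called per comparison (horizontal axis, limma adjusted p under 0.05, of 12437 genes), higher in red and lower in blue. Among genes beyond both parents, higher genes outnumber lower ones in F1 genome x ST04 (380 and 135), and lower ones outnumber higher ones in the reciprocal F1 (999 and 495).

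Expression beyond both parents, often called misexpression, went mostly up in F1 genome x ST04 and mostly down in the reciprocal F1. In F1 genome x ST04, 515 genes lay beyond both parents, 380 above and 135 below. Gene dyak_9576 (FBgn0037761) was at log2 10.82 ± 0.23 in the hybrid (SD, n = 3), 9.76 ± 0.01 in the genome strain and 7.86 ± 0.05 in ST04 (n = 2 each; limma, larger adjusted p = 1.13e-05), with 2 of the 4 parental arrays above the random control spots. Gene dyak_9412 (FBgn0037477) was at 9.10 ± 0.91 in the hybrid, at least 2.36-fold above the mid-parent, and none of the 4 parental arrays rose above the random control spots (limma, larger adjusted p = 0.0149). Its call was lost without either array of the genome strain, without replicate 1 or 2 of the hybrid, and at a threshold of 0.01. Gene dyak_9303 (FBgn0028396) was at 9.53 ± 0.73 in the hybrid against 12.77 ± 0.05 in the genome strain and 11.64 ± 0.20 in ST04 (limma, larger adjusted p = 8.35e-05). Gene dyak_12296 (FBgn0004240) was at 10.83 ± 0.02 against 13.53 ± 0.04 and 12.90 ± 0.33 (limma, larger adjusted p = 7.08e-07). Both genes were also below both parents in the reciprocal F1. The D. yakuba line Cameroon 115 had dyak_9303 at 9.04 and dyak_12296 at 9.57, lower than the hybrid.

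In the reciprocal F1, 1494 genes lay beyond both parents, 495 above and 999 below. The genes below were a median of log2 1.04 away from the mid-parent, the genes above 0.45. Gene dyak_18150 (FBgn0029879) was at 9.48 ± 0.28 in the hybrid (SD, n = 3), at least 3.34-fold above the mid-parent, and none of the 4 parental arrays rose above the random control spots (limma, larger adjusted p = 4.81e-09). Gene dyak_12733 (FBgn0033756) was at 10.90 ± 0.09 against 7.65 ± 0.02 in the genome strain and 9.74 ± 0.09 in ST04 (limma, larger adjusted p = 1.64e-06), with 2 of the 4 parental arrays above the random control spots. Gene dyak_484 (FBgn0028880) was at 7.71 ± 0.33 against 12.47 ± 0.06 and 11.33 ± 0.17 (limma, larger adjusted p = 1.62e-08). Gene dyak_846 (FBgn0032554) was at 7.55 ± 0.36 against 11.88 ± 0.07 and 10.54 ± 0.08 (limma, larger adjusted p = 1.7e-09). For dyak_484 and dyak_846, 1 of the 3 hybrid arrays was above the random control spots.

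Under batch as a block 859 genes lay beyond both parents in F1 genome x ST04 and 2140 in the reciprocal F1, including 514 of the 515 and 1482 of the 1494. In the first batch the counts were 1009 and 2446, including 496 and 1460 of these genes. The block rests on the hybrid arrays alone, so the calls shared under it are no test of a batch effect. In the second batch each hybrid has 1 array and no parent, so no test was possible. The third array of F1 genome x ST04 lay above both parents at 506 of the 604 genes above in the first batch, and below both at 247 of the 405 below. The third array of the reciprocal F1 did so at 747 of 1154 and at 1144 of 1292. Across all genes that array lay above both parents at 42.5% and below both at 25.3%, and the third array of F1 genome x ST04 at 38.0% and 28.4%. The count of F1 genome x ST04 fell to 217 and 223 without replicate 1 and replicate 2 of the genome strain, and to 250 in the fit of 10 arrays. Genes above made up 73.8% of its calls and 60.0% with batch as a block. In the reciprocal F1 they made up 33.1%, but 20.5% with each array centred, 47.2% in the first batch and 81 of 768 among differences of at least 1.5-fold.

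The reciprocal hybrids differed from each other at 5620 genes, 3521 higher and 2099 lower in the reciprocal F1. The lower genes differed more, with a median absolute log2 difference of 0.89 against 0.34 among the higher genes; 931 of them and 86 of the higher genes differed by over 2-fold. Gene dyak_6839 (FBgn0036868) was at log2 13.28 ± 0.20 in the reciprocal F1 and 9.98 ± 0.71 in F1 genome x ST04 (SD, n = 3 each; limma adjusted p = 1.65e-07). Gene dyak_12733 was at 10.90 ± 0.09 and 8.15 ± 0.09 (limma adjusted p = 2.65e-11). Genes dyak_846 and dyak_484 were at 12.06 ± 0.05 and 12.21 ± 0.47 in F1 genome x ST04, and at 7.55 ± 0.36 and 7.71 ± 0.33 in the reciprocal F1 (limma adjusted p = 3.25e-12 and 1.63e-10). In the lower hybrid of each of these 3 genes, 1 of the 3 arrays was above the random control spots, so no fold is given. The fit with batch as a block called 7770 genes, and the first batch alone 7268. The third arrays alone had the same sign at 89.4% of those 7268. Higher genes made up 62.7% of the calls, 45.0% with each array centred and 22.4% among differences of at least 1.5-fold. The median of all genes differed by 0.14 between the hybrids, by 0.06 with centred arrays and by 0.19 under median scaling.

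Genes beyond both parents in both hybrids tended to go opposite ways. Of the 380 genes above both parents in F1 genome x ST04, 222 were below both in the reciprocal F1, against 30.5 under independence, a ratio of 7.27 (two-sided Fisher's exact test over genes, p = 2.11e-148, adjusted over 4 combinations 8.44e-148). In these 222 genes the reciprocal F1 was a median of log2 -0.99 from the mid-parent and F1 genome x ST04 0.55. The other combinations held 18 genes above in both (15.1 under independence), 11 below in F1 genome x ST04 and above in the reciprocal F1 (5.37) and 14 below in both (10.8), with adjusted p of 0.423, 0.0458 and 0.423. Across genes, the deviations of both hybrids from the mid-parent had a correlation of -0.273 and a covariance of -0.033. Simulated unchanged hybrids, in which only the residual spread and the shared parental arrays count, gave 0.428 and 0.005. Hybrids with independent deviations of their own were not simulated, so the value of 0.428 is no reference for them. The set held 314 genes with batch as a block, and in the first batch 396. It fell to 124 under median scaling, to 110 in the fit of 10 arrays, and to 92 and 98 without replicate 1 and replicate 2 of the genome strain.

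In the upper block of array numbers, genes with a large parental difference lay in the median at the level of 1 parent in each hybrid. Among 399 genes called between arrays of the uncrossed lines of each species, with a parental log2 difference of at least 1, the parental position in the upper block (53 genes) was 1.03 ± 0.10 in F1 genome x ST04, the level of the genome strain, and 0.035 ± 0.022 in the reciprocal F1, the level of ST04 (SD, n = 3). In the lower block (346 genes) the positions were 0.647 ± 0.059 and 0.437 ± 0.025. The hybrids thus differed by 0.991 in the upper and 0.210 in the lower block (two-sided exact permutation test, p = 0.1 in each block, the smallest that 3 against 3 arrays allow). In the first batch the positions were 0.979 and 0.0380 in the upper block, over 71 genes, and 0.643 and 0.399 in the lower, over 543 genes. In the second batch each hybrid has 1 array; its upper positions were 1.14 and 0.0573. In windows of 500 array numbers, positions of F1 genome x ST04 ranged from 0.854 to 1.08 in the 6 upper windows and from 0.401 to 0.826 in the 28 lower ones. Those of the reciprocal F1 ranged from -0.099 to 0.0770 and from 0.263 to 0.639. Of all 784 upper genes that differed between the parents, F1 genome x ST04 was called against ST04 alone at 76.3%, against the genome strain alone at 2.81%, between both at 1.91% and beyond both at 3.06%. The reciprocal F1 was called against the genome strain alone at 60.3%, against ST04 alone at 8.42%, between both at 6.25% and beyond both at 10.8%. Of the 4650 lower genes, 46.5% were called against ST04 alone in F1 genome x ST04 and 39.5% against the genome strain alone in the reciprocal F1. These shares by block were not tried under other settings. Whether the block corresponds to a chromosome is not given in the sources used here.

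**Figure D3:**
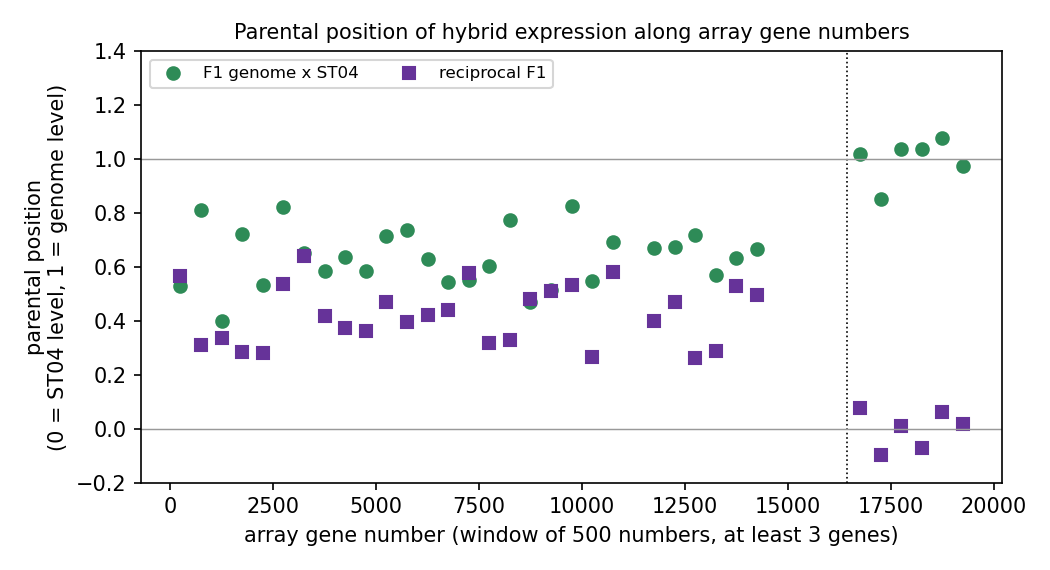
Parental position of hybrid expression (vertical axis, 0 the ST04 level and 1 the level of the genome strain, mean of 3 arrays) in windows of 500 array gene numbers (horizontal axis) with at least 3 genes; the dotted line marks the longest unused stretch of numbers. To its right the hybrids lie near 1 and near 0, and to its left the ranges of 0.401 to 0.826 and 0.263 to 0.639 overlap.

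**Figure D4:**
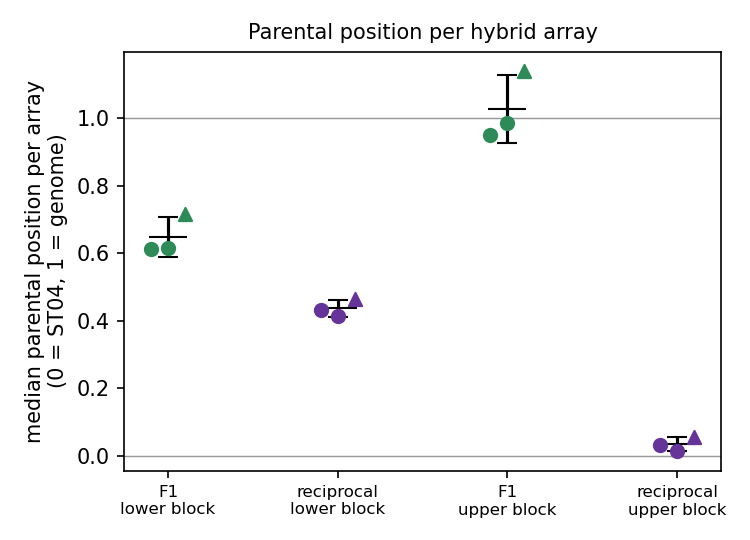
Median parental position of each hybrid array (points; circles first batch, triangles second batch), with mean and SD of 3 arrays as bars, for genes of the lower and the upper block. In the upper block the arrays of F1 genome x ST04 lie between 0.951 and 1.14 and those of the reciprocal F1 between 0.0142 and 0.0573.

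The share of genes called also differed between the blocks. Genes beyond both parents were rarer in the upper block: 2.21% against 4.51% in F1 genome x ST04 (odds ratio 0.478, Fisher's exact test, adjusted p = 3.41e-06) and 9.03% against 12.6% in the reciprocal F1 (odds ratio 0.690, adjusted p = 1.55e-05). The first of these ranged from 0.274 to 0.627 over 34 alternatives and passed the threshold in all 34. The second was not past the threshold with batch as a block (odds ratio 0.879, adjusted p = 0.0672) or in the first batch (0.933, adjusted p = 0.282). In the reciprocal F1 this lay with the genes below both parents, 4.62% of the upper and 8.68% of the lower block (odds ratio 0.509, adjusted p = 3.48e-10). Genes above both made up 4.42% and 3.90% (odds ratio 1.14, adjusted p = 0.345). Divergent genes were not enriched (odds ratio 0.928, adjusted p = 0.751). Calls of F1 genome x ST04 against the mid-parent were more frequent in the upper block (odds ratio 1.27, adjusted p = 1.41e-04), though not past the threshold under median scaling (odds ratio 1.10, adjusted p = 0.266). For the reciprocal F1 against the mid-parent the odds ratio was 0.982 (adjusted p = 0.751), and for the difference between the hybrids 1.12 (adjusted p = 0.0314), with opposite directions within it: 0.849 for genes higher in the reciprocal F1 (adjusted p = 0.00621) and 1.49 for lower ones (adjusted p = 3.48e-10). Shares by direction were not computed under the alternatives. Over 32 alternatives the 1.12 ranged from 0.962 under median scaling (adjusted p = 0.461) to 1.67 with each array centred (adjusted p = 3.95e-24) and passed the threshold in 26. It was 1.07 without replicate 2 of the reciprocal F1 (adjusted p = 0.262). With batch as a block the odds ratio of the reciprocal F1 against the mid-parent was 1.20 (adjusted p = 4.33e-04).

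Genes named as lacking a D. melanogaster ortholog diverged more often between the species, 11 of 154 against 301 of 12283 (odds ratio 3.06, Fisher's exact test, adjusted p = 0.0104). The odds ratio ranged from 1.19 to 9.55 over 40 alternatives and passed the threshold in 28. It was 2.70 without the dimmest 25% of genes (adjusted p = 0.122), and it also missed the threshold without replicate 1 of Bosu (2.63), replicate 2 of ST04 (2.72) or replicate 1 of Quija (2.24). These genes were more often below both parents in F1 genome x ST04, 8 of 154 against 127 of 12283 (odds ratio 5.24, adjusted p = 8.12e-04). For genes beyond both parents in either direction the odds ratio was 2.16 (adjusted p = 0.0391), and it ranged from 1.70 to 5.17 over 34 alternatives and passed the threshold in 22. It was 1.74 without the dimmest genes (adjusted p = 0.301). It missed the threshold without replicate 1 (2.74) or 2 (2.66) of the genome strain, replicate 1 of Bosu (2.28), replicate 1 (2.13) or 2 (1.89) of ST04, and replicate 3 of F1 genome x ST04 (1.83). For the reciprocal F1 beyond both parents the odds ratio was 0.969 (adjusted p = 1). Against the mid-parent, 16.2% of the genes without an ortholog were lower in F1 genome x ST04, against 7.01% of the others (Fisher's exact test, adjusted p = 5.75e-04). In the reciprocal F1 27.9% were higher, against 17.7% (adjusted p = 0.0116). The opposite directions were not past the threshold (adjusted p = 0.742 and 0.277). Genes named as masked on the array were more often beyond both parents in the reciprocal F1 (odds ratio 1.43, adjusted p = 1.09e-04), with 11.5% of them below both against 7.68% of the other genes. They were also more often called against the mid-parent, in F1 genome x ST04 (odds ratio 1.35, adjusted p = 1.09e-04) and in the reciprocal F1 (odds ratio 1.31, adjusted p = 1.07e-04), and between the hybrids (odds ratio 1.32, adjusted p = 4.94e-05). Of the masked genes 18.3% were above the mid-parent in F1 genome x ST04, against 11.5% of the other genes, and 218 of 1146 were below it in the reciprocal F1 (odds ratio 1.65, adjusted p = 5.49e-09). Their odds ratio was 1.13 for species divergence (adjusted p = 0.488) and 1.19 for F1 genome x ST04 beyond both parents (adjusted p = 0.291). The values of the masked genes, of the reciprocal F1 and of single directions in this paragraph were not tried under other settings.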

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

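The tests of the upper block and of background, in the opposite set and in the hybrid arrays of the second batch, were chosen after the results were seen, as was the batch boundary that the correlation of the third arrays rests on. The split counts and the other tests of the opposite set were set before.

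Genes of the upper block with a large parental difference took, in the median, the level of 1 parent in each hybrid, and the difference in position between the hybrids, 0.991 against 0.210 in the lower block, was singled out because the hybrids move to opposite parents. Weaker binding of D. santomea transcripts to probes made for D. yakuba is argued against for the 14 upper genes that were higher in ST04, which gave 0.812 ± 0.016. The other 39 upper genes were lower in ST04, the direction that weaker binding would also give, and this test does not cover them. The batch is argued against by 1.08 between the third arrays and 0.944 between the others, and the normalization by a lowest value of 0.955 over 4 settings. A candidate explanation is a hypothesis, that sons carry a single parental copy of this block, from a different parent in each cross: over 100 upper genes with a parental log2 difference of at least 1, the slope of the difference between the hybrids on the parental difference was 0.798 (95% bootstrap interval 0.680 to 0.910), against 0.180 in the lower block. The slope was nearer to 1, the value that hypothesis names, than to the lower block, which was the criterion set. The slope relates the same differences as the position, and all 53 upper position genes are among the 100. It therefore restates the pattern and is no separate test of the hypothesis. The interval of the slope does not reach 1, but it resamples genes and not arrays. The genes were also chosen on the parental difference itself, and noise in that difference can lower the slope. Over all genes the slopes were 0.868 in the upper and 0.301 in the lower block. Where these genes lie could not be checked, so the hypothesis stays open.

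The set of 222 genes above both parents in F1 genome x ST04 and below both in the reciprocal F1 was singled out because the hybrids move in opposite directions. Among the 396 genes chosen on the first batch alone, the third arrays differed by a median of log2 -1.41 in the same direction, with 99.7% of genes below 0, which argues against the batch and against background, since the random control spots of the third arrays are alike (95th percentiles of 242 and 254). The test of background first set, a median expression percentile under 25 or of at least 50, gave 47.3 and was undecided; the test above replaced it after that was seen. The smallest median over 5 settings of normalization was -1.45, against -1.57 as reported, which argues against normalization. A difference between the crosses in the parent of origin, or in the share of tissues in whole males, stays open and was not tested, since the genes have no names here.

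The hybrids differed at 5620 genes, singled out as a difference between groups under a direct test. The third array of each hybrid, in the second batch, differed from the other replicates by an SD over genes of log2 0.31 to 0.38, against 0.08 and 0.15 between replicates 1 and 2. The deviations of the third arrays correlated between the hybrids, across genes, at 0.608, and with the difference between batches among the lines that were not crossed at 0.558 and 0.355; since the batch boundary was set after the correlations between arrays were seen, this does not test a batch effect, which stays open. Background alone is argued against in F1 genome x ST04, where the SD of deviations in the brightest 25% of genes was 0.869 times that in the dimmest 25%. In the reciprocal F1 this ratio was 0.457, so background may contribute there; the second batch holds 1 array per hybrid, and no biological explanation was tested.

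The random control spots enter the background correction of each array, with all other spots, but are not compared themselves. They were brighter on the first arrays of the reciprocal F1. Their 95th percentile was 943 on replicate 2 and 752 on replicate 1, against at most 527 on any array of a line and 575 on replicate 1 of F1 genome x ST04.

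Other splits of the same samples were counted. For species divergence 1 of the 10 splits of the 6 lines, the real one, gave as many genes (312, highest other 0), and for the reciprocal F1 minus F1 genome x ST04 also 1 of 10 (2916 in a fit of the 6 hybrid arrays, highest other 0); 10 splits are too few for a share under 0.05. For the reciprocal F1 against the mid-parent 1 of 35 splits, the real one, gave as many (1024, highest other 0). This is the smallest share that 35 splits allow, and it was not adjusted over the split counts. Every other split mixes hybrid and parental arrays. The count thus bears only on a difference between these arrays, whatever its cause, and does not test the departure from the mid-parent as such. For F1 genome x ST04 against the mid-parent 2 of 35 gave as many, and chance is not excluded. The real split called 15 genes and another 1242. That other split joins replicate 3 of the hybrid with both ST04 arrays and so follows a structure of the samples, the difference between the parents. These fits of 2 groups count the parental difference as spread and call fewer genes than the fit of 18 arrays.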

How the results depend on the processing

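The first batch alone, the moved ST18 array, the centred arrays and the block and ortholog groups were chosen after the data were seen. Over the results carried through the alternatives 1438 values stayed the same, 71 moved, 13 reversed, 39 lost and 3 gained the threshold. A count stayed the same when it was within 1.5-fold of the reported one. A position did so within its SD over arrays, and other values with the same direction and side of the threshold. Of the 1438, 849 came from leaving out single arrays, not all of which enter a given result. The odds ratios of masked genes, of single directions and, for genes without an ortholog, of comparisons other than species divergence and F1 genome x ST04 beyond both parents were not among the results carried through. Among the named genes 512 were the same and 6 lost the threshold. The difference in position ranged from 0.933 to 1.06 in the upper block and from 0.177 to 0.255 in the lower. Where no cause is named it was not tested.

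Species divergence was 45 genes at a threshold of 0.01, 8691 with replicate number as a block, 7365 with the residual spread within lines, 956 with the line as a random block, 48 in the first batch, and 113, 65, 66, 64 and 78 without the genome strain, Cameroon 115, ST04, ST18 and Quija. Without Bosu, the line farthest from the others of its species, it was 244. Leaving out a line changes both the number of lines and the spread between them, and these were not separated. Spread within lines gives more calls by construction.

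At 0.01, where fewer calls follow by construction, D. santomea lines had 3681 genes, F1 genome x ST04 1118 against the genome strain, 1413 against the mid-parent and 238 beyond both parents, the reciprocal F1 2368 against the mid-parent, and the opposite set 105. With at least 1.5-fold the counts were 2424 between the parents, 672 and 1734 for F1 genome x ST04 against the genome strain and ST04, 2154 and 1475 for the reciprocal F1, 552 and 1244 against the mid-parent, 1834 between the hybrids, 119 and 768 beyond both parents, and 35 in the opposite set.

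With replicate number as a block F1 genome x ST04 had 3282 genes against the genome strain and 817 beyond both parents. With batch as a block it had 3428, 859 and, against the mid-parent, 3648. The first batch alone gave 4915 among D. yakuba lines, 3660, 3988 and 1009 for F1 genome x ST04 against the genome strain, the mid-parent and beyond both, 5465 and 2446 for the reciprocal F1 against ST04 and beyond both, and 396 in the opposite set. The fit of 10 arrays gave 250 for F1 genome x ST04 beyond both parents and 110 in the opposite set, which was 124 under median scaling.

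The odds ratio of the upper block for species divergence reversed to 1.06 with the mean of probes, 1.13 at 0.01, 1.07 with batch as a block and 1.00 with centred arrays, none past the threshold, and passed it at 0.878 with replicate number as a block and 0.820 with the spread within lines. For the reciprocal F1 against the mid-parent it reversed to 1.21 with replicate number as a block, 1.20 with batch as a block, 1.23 in the first batch, 1.15 with the ST18 array moved and 1.21 with centred arrays, all past the threshold, and passed it at 0.820 with at least 1.5-fold. For the difference between the hybrids it reversed to 0.962 under median scaling, and lost the threshold at 1.10 without background correction, 1.10 in the authors' table, 1.01 with the mean of probes and 1.02 without the dimmest genes; with centred arrays it was 1.67. For F1 genome x ST04 against the mid-parent it lost the threshold at 1.10 under median scaling and, with the stricter threshold, at 1.22. For the reciprocal F1 beyond both parents it lost it at 0.879 with batch as a block and 0.933 in the first batch. The difference in position over all genes moved to 0.369 without the dimmest genes. The upper block position of the reciprocal F1 moved to -0.018 without the dimmest genes and to -0.036 with centred arrays. It ranged from 0.011 to 0.059 with each array left out.

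With each array left out, F1 genome x ST04 ranged from 856 to 2564 genes against the genome strain and from 217 to 671 beyond both parents, the opposite set from 92 to 281, and the reciprocal F1 from 2272 to 4585 against ST04 and from 3666 to 6672 against the genome strain. The upper odds ratio ranged from 0.920 to 1.10 for the reciprocal F1 against the mid-parent, where it reversed to 1.01, 1.04 and 1.10 without replicates 1 and 3 of F1 genome x ST04 and replicate 3 of the reciprocal F1, and from 1.07 to 1.34 for the difference between the hybrids, where it was not past the threshold at 1.07 without replicate 2 of the reciprocal F1 (adjusted p = 0.262). A lone array left in a group is assumed to vary like the other groups. The X-linked share, the gene lists and the filter on repeated probes were not run; the position has no value with a replicate or batch block or a minimum of 1.5-fold. Signal over background limits dim genes: on replicate 2 of the reciprocal F1, 79.2% of genes stood above the random control spots.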

Other observations

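The window test below was chosen after the result was seen. Genes that diverged between the species were unevenly spread along the array gene numbers. Between numbers 8500 and 10000, 62 of 1163 genes (5.33%) were called, 26 higher and 36 lower in D. santomea, against 2.22% of the other genes. The region was chosen after its values were seen. The highest share in any window of 500 numbers with at least 100 genes was 6.72%, and a share of 0.006 of 10000 random orders reached it, with 9.49% as the highest. A random order as the cause is argued against, while neighbouring genes that are not independent stay open as a cause. The median SD between lines of a species was 0.22 in this region and 0.24 elsewhere, so a lower spread stays open as a cause, and the median absolute log2 difference between the species was 0.24 and 0.22. Of the line comparisons, 63.5% of its genes differed among D. yakuba lines against 65.4% elsewhere, and 45.1% against 46.5% among D. santomea lines.

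Correlations between arrays could not show whether replicate numbers pair the arrays. Deviations of arrays from their group mean had a median correlation across genes of 0.073 between arrays of the same number in different groups, over 57 pairs that ranged from -0.53 to 0.61, and of -0.064 over 84 pairs of different numbers. In a group of 2 arrays the deviations are exact opposites. Between lines, the values of different numbers are therefore the negatives of those of the same number. Opposite signs of the medians can thus arise by construction. Between the hybrids, arrays of the same number correlated at 0.556, 0.451 and 0.608 for replicates 1, 2 and 3, but replicates 1 and 2 also correlated across numbers, at 0.527 and 0.408. Replicate 3 of each hybrid correlated with replicates 1 and 2 of the other at -0.507 to -0.640. These values cannot be told apart from the shift of the third arrays and do not show a pairing by number. The SD over probes of the difference between replicate arrays of a line was 1.35 to 2.11 times the SD computed from their repeated spots. In the hybrids this ratio was 1.58 to 4.98. The first SD was taken after background correction and normalization, the second on intensities without either. The ratio therefore does not measure the excess over spot noise.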
